A study of Mus musculus with 2 samples.

How the data were processed

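Each sample is 1 Agilent 2-colour microarray that carried a control and a NOGGIN culture of mouse ureters (embryonic day 12.5, 18 h in culture, 10 µg/ml NOGGIN). Per the labels' protocols, 200 ng of total RNA per sample was amplified in a single round and labelled with Alexa Fluor 555 or 647. The direction of each ratio was taken from the dyes in the labels, Alexa Fluor 647 being read in the red channel and 555 in the green. Both arrays lie on 1 slide and were scanned together per the file headers, so slide and scan do not differ between them. Each array carries both conditions.

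The deposited scanner files hold spot intensities on a linear scale, read with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes and the file headers. They give the mean signal, the local background and a processed signal for each channel, and flags for outlying, saturated and dim spots. They also hold a log10 ratio of red over green per spot, which per the file headers is the software's own value. It was checked against the processed signals and not used further. The authors' deposited table holds 1 signed fold change per probe and array, with ratios below 1 written as negative reciprocals. How it was normalised is not given in the sources used here. Its columns have a median of 1. Over 16353 bright probes, its log2 values had a slope of -1.01 on the label-oriented log2 ratio of the same array on both replicates (r = -0.984 and -0.988), against r = -0.718 and -0.722 with the other array. Scale and columns therefore match the scanner files, and its sign is the opposite of what the dyes in the labels give. Which of them is right stays unknown.

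Each array has 39429 probes in 4 spots each, after 22693 and 22629 spots of a filler probe and the control spots were left out. Spots flagged as non-uniform or population outliers in either channel, 3.69% on each array, were left out as well. Median signals of gene spots were 520.7 (control) and 288.3 (NOGGIN) on replicate 1 and 310.6 and 531.8 on replicate 2, so they followed the dye. The background was corrected with normexp (offset 50) on all spots, and each array was normalised with loess, in which control and outlier spots had weight 0. Spots of a probe were averaged. The median SD between spots of a probe was 0.054 and 0.046 on the log2 scale.

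Probes were named through their accessions and a RefSeq gene table of the mouse assembly GRCm38.p6, without versions. A symbol was found for 28328 probes, and 11101 kept the name in the files. No genome build is named in the sources used here, and no coordinates are given. A probe was kept if a share above 0.5 of its spots was well above background on both arrays in the channels of at least 1 condition, which left 26712 probes. A gene with several kept probes, as 4457 had, was represented by the brightest one, and the text says where probes of a named gene disagree. This gave 21337 genes, 15805 of them with a symbol. For 61 genes, 43 of them past the threshold, the probe was not well above background on either array in 1 condition, so their ratios are only bounds. None of them is named in the text.

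Log2 ratios were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, Benjamini-Hochberg over the genes). With 2 arrays there is 1 residual degree of freedom, and moderation added 4.12 prior degrees of freedom around a prior SD of 0.113. A dye effect of a probe cancels in the mean of the exchanged arrays and adds to their spread. A second criterion without a model was a change of at least 1.5-fold with the same sign on both arrays, set beside the count with opposite signs. The 31 gene lists were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), with an estimated correlation beside it, and each list median was placed among 10000 random lists of the same size and similar intensity. The lists hold markers and pathways, 17 genes belong to more than 1 list, and each list's result is in the report.

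The genes named in the report are the 12 largest rises and 12 largest falls among genes past the threshold, up to 4 leading members of each list and 26 genes fixed by name. Predicted or clone names were passed over, 1 among the rises and 0 among the falls. Some genes that this rule names are not reported here. Genes, lists, tests and alternatives were fixed before the data were examined, except where the closing section says otherwise. The alternatives were other background corrections, Agilent's processed signals with median centring, median centring alone, quantile scaling of intensities, other filters on dim probes, other summaries of spots and probes, the deposited table, other forms of the limma test, other thresholds, other forms of the list test, and each array alone. An array alone leaves 0 residual degrees of freedom and gives values with no test.

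The steps were tested on simulated data, made from the real arrays' intensities for the same 21337 genes, with 200 changed genes and an intensity-dependent dye curve. In that simulation of NOGGIN over control, limma recovered 7.46% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 7 of the 131 genes called were unchanged. Most changes of 1.5-fold were thus missed in the simulation. This share does not carry over to the data, since fewer changed genes make the adjusted threshold stricter. Each gene's simulated spread was drawn independently from the prior that limma fitted to the data. The 7 unchanged genes among the calls therefore do not check that prior. Effects shared by many genes of a culture were not simulated. In the data 1701 genes passed, 853 of them with a mean change below 1.5-fold. The list test was tried on log2 ratios drawn at random and independently for each gene, not on the arrays' intensities. A list of 15 genes shifted by 0.5 was called by camera, and 5 of 200 unshifted lists had an unadjusted p under 0.05. Without correlation between genes, this does not check the preset correlation.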

Results

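Gene expression was measured in explanted mouse embryonic ureters cultured with or without NOGGIN, a secreted protein that binds bone morphogenetic proteins (BMPs) and keeps them from their receptors. Ureters of wildtype NMRI embryos of mixed sex were taken at E12.5, when the tube consists of an inner epithelium and an outer mesenchyme that later forms smooth muscle and connective tissue. They were kept for 18 h on transwell membranes in medium with 10 µg/ml NOGGIN or in medium without it. The data are 2 Agilent 2-colour microarrays, replicates 1 and 2, and each array carried RNA of 1 control culture and 1 NOGGIN culture. The dyes were exchanged between them. On replicate 1 the control carried the red dye and the NOGGIN sample the green one, and on replicate 2 the other way round. Between 67.3% and 74.3% of the gene spots were well above background, depending on the channel, and 0 spots were saturated. The number of arrays, 2, limits the precision of every value. Nothing in the labels says how many embryos entered a culture or that the replicates came from separate litters. The spread between these samples may thus be technical. The limma p-values rest on it only in part, since moderation added 4.12 prior degrees of freedom from all genes to the 1 residual one. Camera p-values with the preset correlation compare a list's genes with the other genes and do not measure the spread between cultures.

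The comparison asks which transcripts differed between ureters cultured with and without the BMP antagonist. The lists with the smallest p-values were the target genes of BMP signalling and the smooth muscle genes, and they ran opposite to each other. The list of BMP ligands, receptors and antagonists went in both directions. Log2 ratios below are NOGGIN-labelled over control-labelled channel, following the dyes in the labels, as mean ± SD over the arrays (n = 2), and "higher" and "lower" refer to the NOGGIN-labelled channel. Id2, an inhibitor of basic helix-loop-helix factors and a direct target of BMP signalling, was higher by 2.73 ± 0.87, a 6.62-fold difference (adjusted p = 0.00975, limma). Gdf6, a BMP family ligand, was lower at -3.07 ± 0.38, an 8.39-fold difference (adjusted p = 0.00338). The authors' deposited table has the opposite sign on both arrays. There the signed fold change of Id2 is -4.19 on replicate 1 and -10.5 on replicate 2, that of Smad9 -5.26 and -6.74, and that of Acta2 2.30 and 2.22. The direction is therefore not settled by these data. The fall of BMP targets that a BMP antagonist would give goes against the labels. It goes with the deposited table only if that table holds NOGGIN over control, which is not stated. Turning the sign turns each "higher" below into "lower" and the reverse, with the same size. Counts of higher and lower then change places, while totals, sizes and p-values stay as they are.

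Of 21337 genes tested, 1701 (7.97%) passed an adjusted p of 0.05 in limma, 842 higher and 859 lower. A change of at least 1.5-fold in the same direction on both arrays was seen for 618 genes, 288 higher and 330 lower, all of which were among the 1701. Only 8 genes changed 1.5-fold on both arrays in opposite directions. At 2-fold the counts were 74 higher, 105 lower and 0 in opposite directions. Across genes, which are not independent replicates, the arrays' log2 ratios had a Pearson r of 0.702 and a Spearman rho of 0.53. Where each array was only centred on its median, without the intensity-dependent loess step, 0 genes passed in limma, against 3572 with an unadjusted p under 0.05. Still, 621 genes changed 1.5-fold in the same direction on both arrays there, 577 of them among the 618, and 195 in opposite directions.

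**Figure D1:**
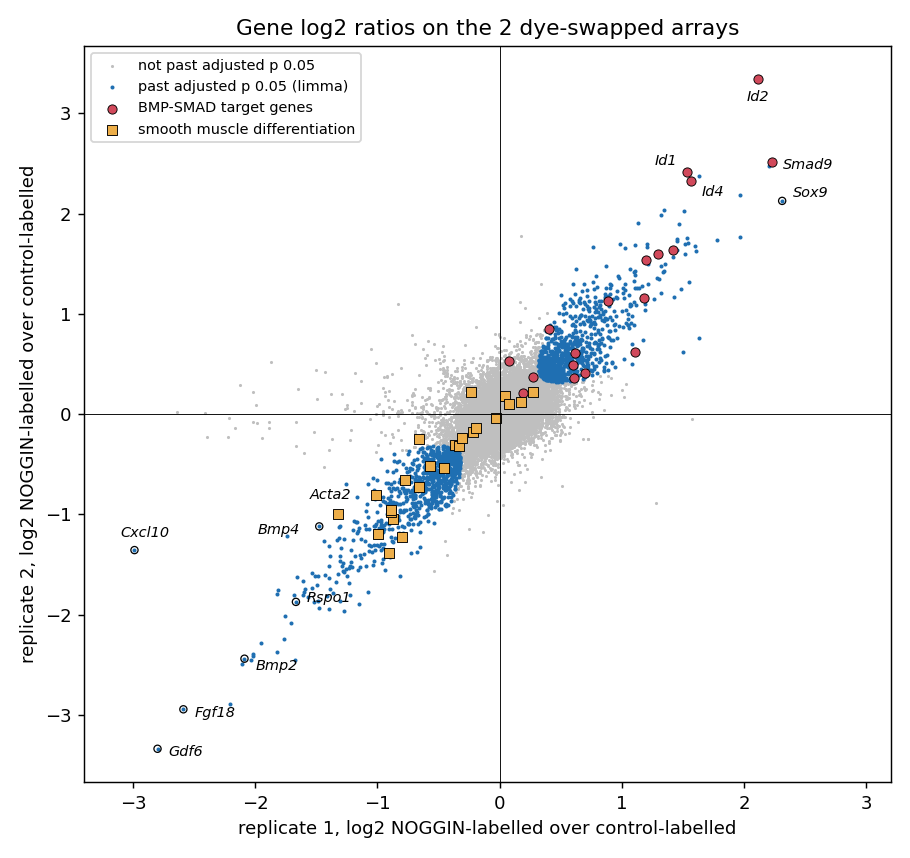
Log2 ratio of the NOGGIN-labelled over the control-labelled channel of each of the 21337 genes on replicate 1 (x axis) and replicate 2 (y axis; blue, past an adjusted p of 0.05 in limma; red circles, BMP-SMAD targets; orange squares, smooth muscle genes). The 842 higher genes lie at the upper right and the 859 lower ones at the lower left, with Id2 at 2.11 and 3.34 and Gdf6 at -2.80 and -3.34.

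BMP-SMAD target genes, which SMAD transcription factors switch on when BMPs signal, were higher as a group. Of 18 measured members 15 were higher, 0 lower and 3 did not pass (17 higher and 0 lower adjusted over the list alone), and 11 were higher by at least 1.5-fold on both arrays. Smad9, a receptor-activated SMAD, was higher by 2.37 ± 0.20. The Id genes Id1, Id3 and Id4 were higher by 1.98 ± 0.62, 1.45 ± 0.21 and 1.94 ± 0.53. The inhibitory SMADs Smad6 and Smad7 were higher by 1.01 ± 0.17 and 0.55 ± 0.082 and the homeobox gene Msx2 by 1.17 ± 0.014. The median of the list was 0.94, and camera, which compares a list with all other genes, gave an adjusted p of 9.15e-16 with a preset correlation. With an estimated correlation the adjusted p was 0.724. That form of camera has only the 1 residual degree of freedom of the arrays, so it can hardly call any list here.

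Genes of BMP ligands, receptors and antagonists changed in both directions. Of 25 measured members 5 were higher, 6 lower and 14 did not pass (6 and 7 adjusted over the list alone). The ligand gene Bmp2 was lower at -2.26 ± 0.25 and Bmp4, the main BMP of the ureteric mesenchyme, at -1.30 ± 0.25. Chrdl1, which encodes a secreted BMP antagonist, was higher by 1.87 ± 0.15. The list median was -0.049 and camera did not separate it from other genes (adjusted p = 0.814).

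Smooth muscle differentiation genes were lower as a group. Of 24 measured members 0 were higher, 12 lower and 12 did not pass (1 and 16 adjusted over the list alone). The contractile genes Acta2, Tagln, Cnn1 and Myh11 were at -1.16 ± 0.23, -1.09 ± 0.14, -0.93 ± 0.061 and -0.91 ± 0.14. Nexn, which encodes an actin-binding protein, and Tnnt2, a troponin gene, were at -1.14 ± 0.34 and -1.01 ± 0.30. Myocd, the coactivator that drives the contractile genes, did not pass in limma, with 0.15 ± 0.038 (adjusted p = 0.294). Its mean log2 signal was low, at 7.42, so this does not show that it was unchanged. The list median was -0.48 (camera adjusted p = 7.27e-09; adjusted p = 0.724 with an estimated correlation).

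**Figure D2:**
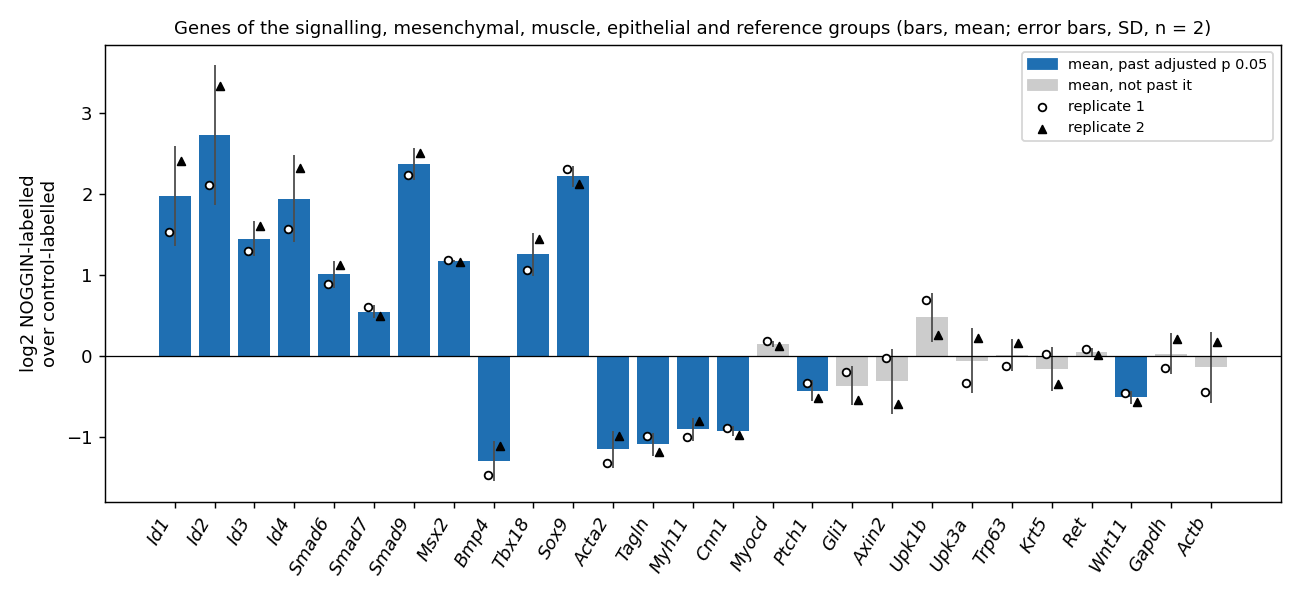
Log2 ratio of the NOGGIN-labelled over the control-labelled channel for genes named in advance and Smad9 (bars, mean; error bars, SD, n = 2; circles, replicate 1; triangles, replicate 2; blue, past an adjusted p of 0.05 in limma). The BMP targets from Id1 to Msx2 lie above 0 and Bmp4, Acta2, Tagln, Myh11 and Cnn1 below 0 on both arrays, while Myocd, Gapdh and Actb did not pass.

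Extracellular matrix and fibroblast genes were also lower, with 1 of 22 measured members higher, 11 lower and 10 not passing (2 and 13 adjusted over the list alone). Tnc, Col3a1 and Igfbp5 were at -0.91 ± 0.059, -0.89 ± 0.19 and -0.89 ± 0.22. The member that passed as higher over all genes was Postn, a matrix protein gene, by 0.92 ± 0.21. The median was -0.35 (camera adjusted p = 8e-05; adjusted p = 0.724 with an estimated correlation). Among TGF-beta targets 4 of 13 were lower and 0 higher (6 and 0 adjusted over the list alone), led by Ccn1 at -1.15 ± 0.23, while Ccn2 did not pass at -0.60 ± 0.35. The TGF-beta list had a median of -0.19 (camera adjusted p = 0.00277; adjusted p = 0.724 with an estimated correlation), with -0.25 on replicate 1 and -0.35 on replicate 2. Of 15 stress and immediate early genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone). Jun and Ier2 were at -0.73 ± 0.086 and -0.59 ± 0.0016. The stress list had a median of -0.18 (camera adjusted p = 0.00164; adjusted p = 0.724 with an estimated correlation), with -0.28 on replicate 1 and -0.13 on replicate 2.

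Regulator genes of the undifferentiated ureteric mesenchyme were higher as a list, though most single members did not pass. Of 17 measured regulators 6 were higher, 2 lower and 9 did not pass (10 and 2 adjusted over the list alone). Sox9 was higher by 2.22 ± 0.13, Tbx18, a marker of the ureteric mesenchyme, by 1.25 ± 0.27 and Gata6 by 0.99 ± 0.14. Bmp4, which also belongs to the ligand list, was among the lower members. The median was 0.31 (camera adjusted p = 0.00164; adjusted p = 0.724 with an estimated correlation). Cartilage and bone genes shared this direction, with 6 of 12 higher and 0 lower (7 and 1 adjusted over the list alone). Hapln1, which links aggrecan to hyaluronan, was higher by 1.33 ± 0.026, and Ibsp, a bone matrix gene, by 0.95 ± 0.22. The size for Ibsp is uncertain, since its control channel was well above background on 1 of 2 arrays and its value ranged from 0.79 to 1.88 over the alternatives. Col9a1 was higher by 0.82 ± 0.11, but its other probe gave -0.049. The cartilage list had a median of 0.36 (camera adjusted p = 0.0069; adjusted p = 0.724 with an estimated correlation), and it did not pass in camera on ranks (adjusted p = 0.0681).

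Urothelial differentiation genes were higher as a list, though few single members passed. Of 19 measured members 4 were higher, 1 lower and 14 did not pass (7 and 2 adjusted over the list alone). Pparg, a nuclear receptor gene, was higher by 2.00 ± 0.53, Sprr1a by 0.96 ± 0.31 and Upk2, a uroplakin of the luminal membrane, by 0.61 ± 0.23. The uroplakin genes Upk1a, Upk1b and Upk3a gave 0.58 ± 0.36, 0.48 ± 0.31 and -0.058 ± 0.40 and did not pass. Nor did Trp63 and Krt5, genes of basal cells, at 0.015 ± 0.20 and -0.16 ± 0.27. The median was 0.24 (camera adjusted p = 0.00782; adjusted p = 0.724 with an estimated correlation), with 0.41 on replicate 1 and 0.12 on replicate 2.

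Lists of kidney and ureteric bud cells were lower or not separated from other genes. Of 12 measured members of the ureteric bud tip list 4 were lower and 0 higher (4 and 1 adjusted over the list alone). Whole ureters were measured, so these values do not place a change in bud tips. Gfra3, Wnt9b and Wnt11 were at -0.87 ± 0.0023, -0.69 ± 0.27 and -0.51 ± 0.077. Ret, the receptor gene that marks bud tips, did not pass at 0.047 ± 0.050. The tip list passed narrowly (camera adjusted p = 0.0476; adjusted p = 0.791 with an estimated correlation), and its median of -0.105 rested on replicate 2 (-0.26), since it was 0.019 on replicate 1. It did not pass with a normexp offset of 0 (adjusted p = 0.054), the mean of each gene's probes (0.0628), median centring (0.119), ranks (0.129) or matched random lists (0.154). Renal stroma genes had 4 of 10 lower and 0 higher (5 and 0 adjusted over the list alone). They were Fibin at -1.37 ± 0.23, Ntn1 at -1.22 ± 0.21, Smoc2 at -1.17 ± 0.27 and Foxd1, the stromal progenitor factor, at -0.80 ± 0.20. The stroma list had a median of -0.12 (camera adjusted p = 0.047; adjusted p = 0.788 with an estimated correlation) and did not pass in camera on ranks (adjusted p = 0.335). Its median was -0.059 on replicate 1 and -0.18 on replicate 2. Nephron progenitor genes, with 1 of 15 higher and 4 lower (1 and 6 adjusted over the list alone), did not pass (camera adjusted p = 0.231). Their median, 0.0013, and their mean, -0.18, differ in sign. Meox1 was at -1.74 ± 0.086, Lhx1 at -0.75 ± 0.19 and Itga8 at 0.76 ± 0.085. Collecting duct genes had 1 of 10 lower and 0 higher (3 and 1 adjusted over the list alone), namely Avpr2 at -0.73 ± 0.28, with a median of -0.15 (camera adjusted p = 0.122). Against matched random lists the collecting duct list passed (adjusted p = 0.0426).

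Of the lists for other signalling pathways, FGF-ERK targets passed in camera and hedgehog genes did not. Hedgehog genes passed against matched random lists (adjusted p = 0.0359). Of 13 FGF-ERK targets 4 were lower and 0 higher (5 and 0 adjusted over the list alone). The feedback inhibitors Spry2, Dusp6 and Spry1 were at -0.80 ± 0.17, -0.67 ± 0.21 and -0.67 ± 0.19. The FGF list passed with a median of -0.17 (camera adjusted p = 0.0069; adjusted p = 0.724 with an estimated correlation). That median was -0.027 on replicate 1 and -0.23 on replicate 2. Hedgehog pathway genes did not pass (median -0.11, -0.028 on replicate 1 and -0.20 on replicate 2, camera adjusted p = 0.168), with 1 of 14 higher and 2 lower (2 and 5 adjusted over the list alone). The receptor and target gene Ptch1 was lower at -0.43 ± 0.13 and Gli2 at -0.43 ± 0.052, while Gli1 at -0.37 ± 0.24 did not pass. The call of Ptch1 was lost in the separate-channel model (adjusted p = 0.14), and that of Gli2 with Agilent's processed signals centred on their median and with the deposited table's values.

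Canonical WNT targets did not pass as a list (camera adjusted p = 0.876), with 4 of 17 higher and 2 lower (4 and 3 adjusted over the list alone). Their median, -0.037, and mean, 0.028, differ in sign. Dkk2 and Wif1, which encode secreted WNT antagonists, were higher by 1.24 ± 0.20 and 0.93 ± 0.071, and Tnfrsf19 was lower at -1.27 ± 0.33, with a second probe at -0.33. Axin2, the usual readout gene, did not pass at -0.31 ± 0.40. Of 14 WNT ligand and antagonist genes 1 was higher and 5 were lower (3 and 6 adjusted over the list alone). Rspo1 and Rspo2, which encode WNT-enhancing R-spondins, were at -1.77 ± 0.15 and -0.89 ± 0.093, Wnt6 at -1.40 ± 0.020, and Sfrp2 was higher by 0.92 ± 0.033 (list median -0.095, camera adjusted p = 0.103). Retinoic acid pathway genes had 1 of 14 higher and 2 lower (1 and 3 adjusted over the list alone), led by Aldh1a2, a retinoic acid synthesis enzyme gene, at -0.88 ± 0.31 (list median -0.14, camera adjusted p = 0.18). Against matched random lists the retinoic acid list passed (adjusted p = 0.00564). NOTCH pathway genes had 2 of 13 lower and 0 higher (2 and 0 adjusted over the list alone). These were the ligand gene Dll1 at -1.02 ± 0.078 and the target gene Heyl at -0.56 ± 0.13. The NOTCH list did not pass (camera adjusted p = 0.57), and its median, 0.056, and mean, -0.089, differ in sign.

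Proliferation genes were higher by small amounts. Of 22 measured members 7 were higher, 0 lower and 15 did not pass (11 and 0 adjusted over the list alone), and 0 of them reached 1.5-fold on both arrays. Mki67 was higher by 0.51 ± 0.030, Ccnb1 by 0.47 ± 0.028, Bub1b by 0.46 ± 0.068 and Kif11 by 0.46 ± 0.12, all of which act in mitosis or mark dividing cells. The median was 0.24 (camera adjusted p = 2.55e-04; adjusted p = 0.724 with an estimated correlation). Of 10 genes of D cyclins and CDK inhibitors 1 was higher and 1 lower (1 and 1 adjusted over the list alone). Cdkn1a was lower at -0.86 ± 0.19, though its other probe gave -0.0042, and Cdkn2c was higher by 0.52 ± 0.11. That list did not pass (camera adjusted p = 0.809), and its median, 0.041, and mean, -0.023, differ in sign. Of 13 p53 and apoptosis genes 1 was higher and 3 lower (2 and 5 adjusted over the list alone), with Pmaip1, a pro-apoptotic gene, at -1.16 ± 0.37 (list median -0.063, camera adjusted p = 0.18). Hypoxia and glycolysis genes had 1 of 15 lower, Adm at -0.39 ± 0.090, and 0 higher (3 and 0 adjusted over the list alone; list median -0.063, camera adjusted p = 0.306).

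Among the 12 largest rises and 12 largest falls, several genes belonged to no list fixed in advance. The neuropeptide Y receptor gene Npy1r was higher by 2.34 ± 0.19, Crhbp, whose product binds corticotropin-releasing hormone, by 1.76 ± 0.027, Brinp3 by 1.69 ± 0.49 and Iigp1, an interferon-inducible GTPase gene, by 1.68 ± 0.30. The growth factor gene Fgf18 was at -2.77 ± 0.25, the protease gene Adamts16 at -2.55 ± 0.48, with a second probe at -0.98, and the adenylyl cyclase gene Adcy7 at -2.30 ± 0.27. Tmem132c was at -2.25 ± 0.30, Lrig1 at -2.22 ± 0.28, the arginine methyltransferase gene Prmt8 at -2.21 ± 0.27 and Lrrc55 at -2.11 ± 0.23. Thbd, which encodes thrombomodulin, was at -2.10 ± 0.39 and Stra6l at -2.06 ± 0.55. The adjusted p of these genes lay between 0.00338 and 0.00909. Cxcl10, an interferon-inducible chemokine gene, was at -2.17 ± 1.15 (adjusted p = 0.0325), with -2.99 on replicate 1 and -1.36 on replicate 2. Its call was lost with robust moderation and in the separate-channel model, where the adjusted p reached 0.162.

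Markers of other cell types were mostly not separated from other genes. Macrophage markers were the exception. None of the 14 passed singly over all genes (1 higher and 7 lower adjusted over the list alone), but the list was lower with a median of -0.28 (camera adjusted p = 0.00272; adjusted p = 0.724 with an estimated correlation). The shift was uneven, with a median of -0.43 on replicate 1 and -0.12 on replicate 2. Lyz2, the lysozyme gene, gave -0.53 ± 0.39, and C1qb, a complement gene, -0.37 ± 0.16, and neither passed. Of 15 endothelial markers 0 passed in either direction, also adjusted over the list alone (median 0.070, camera adjusted p = 0.0773), and Cdh5 gave 0.34 ± 0.13. Blood cell markers had 1 of 10 higher, Epor at 0.43 ± 0.13, and 0 lower (1 and 0 adjusted over the list alone). Neither they (camera adjusted p = 0.906, median -0.012, mean 0.0075) nor the neural and glial markers passed (camera adjusted p = 0.985, median 0.011). In the latter Stmn2 and Gap43, genes of growing neurons, were higher by 0.70 ± 0.093 and 0.60 ± 0.00044, while Foxd3 and Dbh were lower at -0.56 ± 0.27 and -0.42 ± 0.11, which made 2 of 14 in each direction (2 and 3 adjusted over the list alone). Mesothelium and gonadal markers had 1 of 8 lower and 0 higher (1 and 1 adjusted over the list alone), with Wt1 at -0.81 ± 0.39 (camera adjusted p = 0.957, median 0.050, mean -0.025). Skeletal muscle markers had 1 of 8 lower and 0 higher (2 and 0 adjusted over the list alone), the actin gene Acta1 at -1.19 ± 0.17, while Myod1 gave -0.083 ± 0.0097 (list median -0.082, camera adjusted p = 0.0805).

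Of the sex-linked genes, Xist, which is transcribed from the inactive X chromosome, was higher by 0.65 ± 0.30 (adjusted p = 0.0397), a call lost with the deposited table's values and in the separate-channel model, and the Y-linked genes Uty, Eif2s3y and Ddx3y did not pass, with -0.23 ± 0.090, -0.19 ± 0.18 and -0.13 ± 0.055. A second probe of Uty gave 0.035. Thus 1 of 5 was higher and 0 lower (1 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.659, median -0.13, mean 0.019). Of 15 reference genes 0 passed in either direction, also adjusted over the list alone (median 0.024, camera adjusted p = 0.833). Gapdh was at 0.028 ± 0.26 and Actb at -0.14 ± 0.44, and for both the arrays had opposite signs. Of the 7 probes of Gapdh, 1 had a mean above 0.

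**Figure D3:**
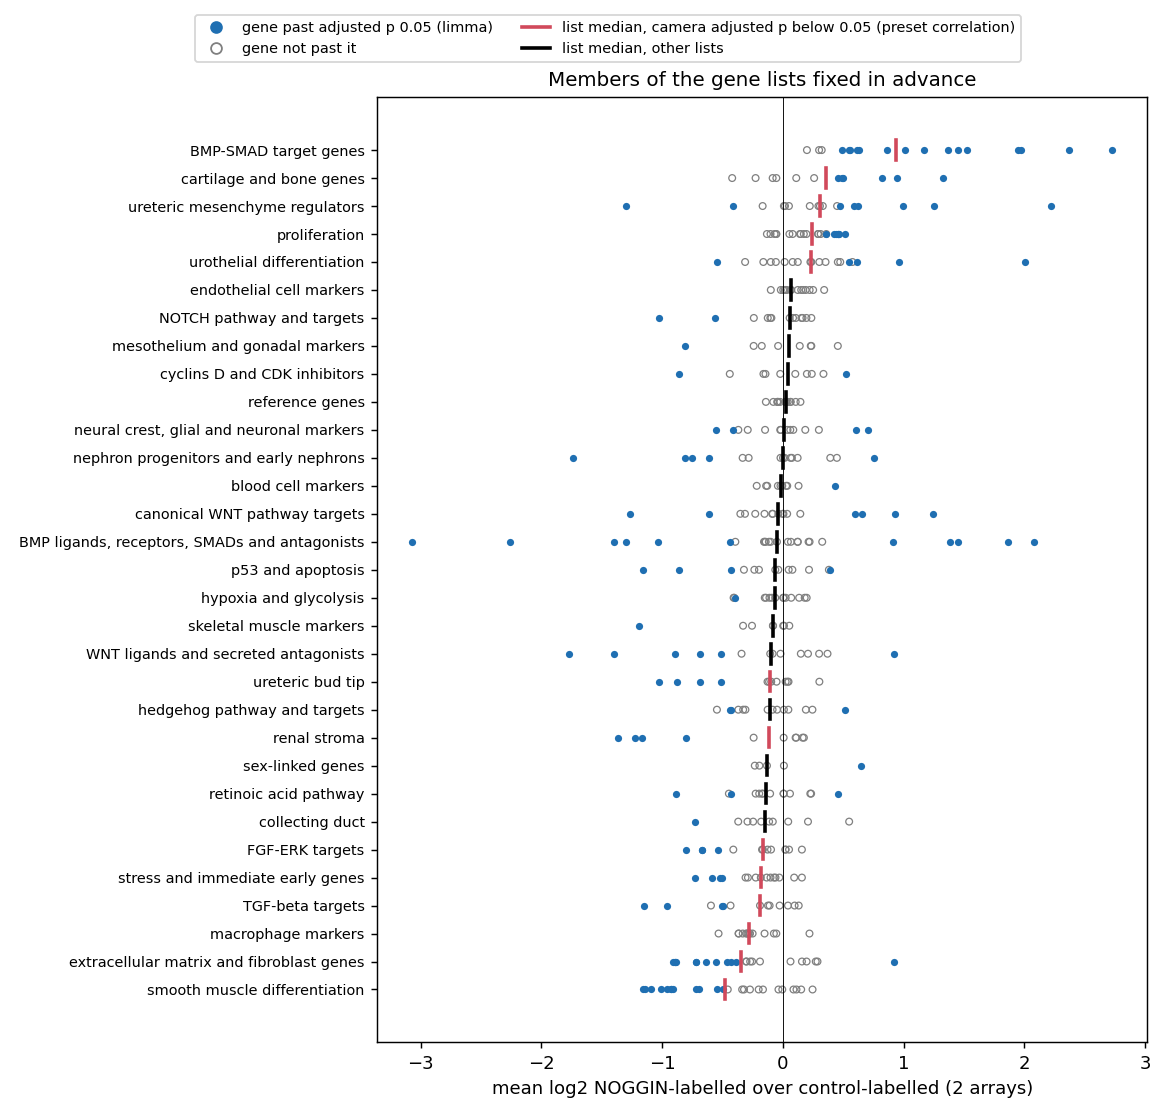
Mean log2 ratio (x axis, NOGGIN-labelled over control-labelled, 2 arrays) of each measured member of the 31 gene lists fixed in advance (filled blue, past an adjusted p of 0.05 in limma; strokes, list medians, red where camera passed with the preset correlation). The BMP-SMAD targets have the highest median, 0.94, and the smooth muscle genes the lowest, -0.48.

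With the preset correlation 13 of the 31 lists passed, 5 higher and 8 lower. With a correlation estimated from the 2 arrays, which leave 1 residual degree of freedom, 0 lists passed. The smooth muscle list lost its call there although its estimated correlation, -0.036, lay below the preset 0.01. The matrix (-0.013), cartilage (-0.091), proliferation (-0.039) and stress (-0.067) lists also lay below it. For these lists the loss therefore does not show that correlation between genes makes the call. The other lists that passed had estimates above it, from 0.029 (mesenchyme) to 0.67 (bud tip). For them this cannot be told from 1 residual degree of freedom. Of the other genes named, Heyl, Avpr2, Wt1, Bub1b, Kif11, Adm, Epor, Foxd3 and Dbh passed in the analysis given and lost the call under at least 1 alternative other than median centring.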

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

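Turning all signs as in the deposited table was added after the data had been seen, and the other alternatives were fixed before. Where the cause of a difference is not given, it was not tested. A direction counts as reversed only where the value passed in the analysis reported or in the alternative.

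Apart from median centring and the other threshold, between 1418 and 2002 genes passed, and 2139 probes where probes were tested one by one. Signal over background limits the gene number: 20409 genes were tested with both channels well above it, and 32089 with no filter. Turning the signs gives 859 genes higher and 842 lower. Of the 104 named genes that passed, 0 changed sign, and 80 kept the call under every setting that gave them a test apart from median centring (12 settings, or 11 for Ibsp and Eda2r). The other 24 included Cxcl10, Gli2, Ptch1, Sp5, Crabp1, Aldh1a1, Phlda1, Heyl, Ltbp2, Adamts18, Avpr2, Wt1, Spp1, Bub1b, Kif11, Ccng1, Adm, Atf3, Chac1, Epor, Foxd3, Dbh and Xist. A gene with opposite signs on the 2 arrays cannot pass in this limma fit, so each array alone could not show a change of sign. Quantile scaling of intensities left all 1701 calls as they were, so it could not lose any. Many of these genes were also named for large changes in the same data. Another 11 named genes did not pass in the analysis reported and passed under at least 1 setting, among them Ccn2, Upk1a, Aqp3, Aqp4, Hk2, Pfkfb3, Actn2, Stra6 and Cdh5. Ccn2 and Upk1a did so with no background subtraction (adjusted p = 0.0411 and 0.0475) and with an intensity trend (adjusted p = 0.0417 and 0.047), and Cdh5 with that trend (adjusted p = 0.0452).

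With median centring in place of loess 0 genes passed and r between the arrays fell to 0.459. There 195 genes changed 1.5-fold in opposite directions against 8 with loess, so dye differences that depend on intensity stayed in. In the same direction 621 genes changed 1.5-fold on both arrays, and 577 of them were shared with the 618 under loess. The bud tip list no longer passed (-0.12, camera adjusted p = 0.119), while 12 lists did.

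With Agilent's processed signals centred on their median, a change of both signals and normalisation, 949 genes changed 1.5-fold on both arrays, r was 0.718, and skeletal muscle markers passed (-0.17, adjusted p = 0.0436). With the deposited table, turned to the labels, these were 946 genes and r = 0.691. Without the filter on dim probes r was 0.657, and WNT ligands (-0.15, adjusted p = 0.0173), endothelial markers (0.067, adjusted p = 0.0274) and skeletal muscle markers (-0.054, adjusted p = 0.0478) passed. With the mean of a gene's probes r was 0.71 and the bud tip list did not pass (-0.11, adjusted p = 0.0628), nor did it with a normexp offset of 0 (-0.12, adjusted p = 0.054). An adjusted p of 0.1 let 2691 genes pass, and 179 genes changed 2-fold.

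With an estimated correlation, where the list test has 1 residual degree of freedom and can hardly call a list, 0 lists passed. The medians are unchanged by construction: BMP targets 0.94, smooth muscle -0.48, mesenchyme 0.31, FGF -0.17, TGF-beta -0.19, urothelium 0.24, matrix -0.35, cartilage 0.36, proliferation 0.24, stress -0.18 and macrophages -0.28 (adjusted p = 0.724 each), bud tip -0.11 (adjusted p = 0.791) and renal stroma -0.12 (adjusted p = 0.788). On ranks bud tip (-0.11, adjusted p = 0.129), renal stroma (-0.12, adjusted p = 0.335) and cartilage (0.36, adjusted p = 0.0681) did not pass. Against matched random lists hedgehog (-0.106, adjusted p = 0.0359), retinoic acid (-0.136, adjusted p = 0.00564) and collecting duct (-0.147, adjusted p = 0.0426) passed and bud tip did not (-0.105, adjusted p = 0.154).

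Each array alone allows no test. It gave 948 to 1087 genes changed 1.5-fold, since a single array had to pass. List medians lay at 0.986 to 0.9995 for BMP targets, -0.071 to 0.0054 for BMP ligands, 0.2565 to 0.311 for mesenchyme, -0.116 to 0.070 for NOTCH, -0.353 to -0.2545 for TGF-beta, -0.200 to -0.131 for collecting duct, -0.025 to -0.0066 for nephron, -0.408 to -0.380 for matrix, -0.08675 to -0.057 for hypoxia, 0.053 to 0.131 for endothelium, -0.179 to -0.124 for skeletal muscle, 0.334 to 0.357 for cartilage and 0.046 to 0.072 for D cyclins. They also spread for hedgehog (-0.200 to -0.028), canonical WNT (-0.131 to 0.056), WNT ligands (-0.172 to -0.0375), FGF (-0.229 to -0.027), urothelium (0.120 to 0.409), renal stroma (-0.176 to -0.059), stress (-0.283 to -0.126), macrophages (-0.431 to -0.116), p53 (-0.0935 to -0.037), blood (-0.052 to 0.026), neural (-0.038 to 0.114), mesothelium (-0.039 to 0.123), sex-linked (-0.168 to -0.065) and reference genes (-0.0074 to 0.0875). The bud tip list, at -0.256 to 0.019, reversed without replicate 2.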

Other observations

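The tests of the direction and of Xist were chosen after the result was seen. Those of the interferon genes were fixed before the values of their list were read, though the pattern itself was noticed in the data.

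Many interferon-stimulated genes, which cells switch on in antiviral responses, were lower in the NOGGIN-labelled channel of replicate 1 and near 0 on replicate 2. Genes chosen after their values were seen are Ifit1 (-2.23 and -0.23), Oasl2 (-2.21 and -0.041), Usp18 (-1.88 and -0.14) and Bst2 (-1.94 and -0.23), none of which passed in limma. A list of 30 other such genes was then written, of which 25 were measured, and 24 were lower on replicate 1 and 13 on replicate 2. At least 1.5-fold lower were 9 of them on replicate 1 and 0 on replicate 2, among them Xaf1 (-1.65 and 0.25) and Rsad2 (-1.43 and 0.42). Of these only Cmpk2 passed (adjusted p = 0.0472). Other interferon-inducible genes differed: Iigp1 was higher on both arrays (1.47 and 1.90), Cxcl10 lower on both (-2.99 and -1.36), and Rtp4 and Gbp2 were higher on replicate 2 (1.10 and 0.65).

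The 8 genes that changed 1.5-fold on both arrays in opposite directions, seen only after the values were, fall into different kinds. All of them but Hes5 were higher in the red channel of both arrays. Slc45a3 (-0.72 and 0.79), Lrsam1 (-0.63 and 0.65) and the clone AK032482 (-0.69 and 0.70) are among the brightest probes, with mean log2 signals of 15.9, 16.1 and 16.2. Their values on the arrays are nearly equal in size. Another clone, AK012244, gave -0.59 and 0.73. Gbp2 (-1.05 and 0.65) and Rtp4 (-0.83 and 1.10) are interferon-inducible genes, Cd52 (-0.60 and 0.59) is a leukocyte gene and Hes5 (1.28 and -0.89) a NOTCH target.

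The direction of the BMP response is open. By the dyes in the labels 15 of 18 BMP target genes were higher with NOGGIN, which blocks BMPs, while the deposited table has a slope of -1.01 on both arrays. An exchange of the dye labels of both arrays would give this. An exchange on a single array would not, since r between the arrays was 0.702. A block of BMPs would lower their targets, yet 15 were higher and 0 lower by the labels. Together with the sign of the deposited table this argues against a true rise and against the labels' direction. The dyes actually used remain unknown, so the labels' direction was kept, and every direction in the text may be the reverse.

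The lower interferon genes on replicate 1 may reflect an interferon response in its control-labelled culture. The list median there was -0.506 (quartiles -0.742 to -0.274), below all of the matched random lists (their central range was -0.0812 to 0.104), and it was -0.01 on replicate 2, at percentile 45.6. A dye bias alone is not the cause, since it would turn the sign on replicate 2 and keep the size. A dye bias added to a shift shared by both replicates could give both medians, and 2 arrays cannot tell this apart. Such a response would not account for the higher Iigp1 or for Rtp4 and Gbp2 on replicate 2. A different share of macrophages stays open, because their markers on that array had a lower quartile of -0.544 and the interferon median does not lie below it.

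The higher Xist could come from more female embryos in the NOGGIN-labelled cultures, as the sexes were mixed. Of the Y-linked genes 3, namely Uty, Eif2s3y and Ddx3y, were lower on both arrays, while Kdm5d was not. None of them passed, so this cannot be told. A dye bias alone is not the cause, since Xist was higher on both dye-swapped arrays, by at least 0.435.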
